A study of Homo sapiens with 3 samples.

How the data were processed

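The series holds 3 libraries from the lung cancer line 95D, 1 each for control, glucose-deficient and glutamine-deficient culture. The labels' protocols describe RNA pulled down with the long non-coding RNA DAMER for all 3, while the sample titles name plain RNA sequencing, so whether the control library is a pulldown is open. Per the labels' protocols, cells were seeded for 24 h and deprived for 48 h in medium with 10% dialyzed serum. Whether the control medium also had dialyzed serum is not given in the sources used here. Per the labels' protocols, 50 pmol of biotinylated DAMER was bound to streptavidin beads for 30 min and held with lysate for 1 h at 4 °C, and ribosomal RNA was depleted before paired sequencing of 150 nt. Per the submitters' processing notes, reads were aligned to hg38 with HISAT2 2.0.5. How regions were called and chosen, which annotation was used and whether counting used strand are not given in the sources used here.

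The deposited values are in RPM per the file headers, not the counts that the design assumed, so the alternative written for normalized values became the main analysis. The deposited series table sets 2 blocks side by side, each with a gene, a control value and the value of 1 deprived library. A block lists 12718 or 12710 distinct regions without coordinates, and 2804 genes had more than 1 entry. In each block 691 entries, of 14338 and 14333, name no gene and stayed out of the gene comparisons. All 5932 gene identifiers matched the gene name table and 5796 the GENCODE release 29 annotation, the source of all coordinates. The label of the glutamine-deficient sample names the glucose column, so its own deposited file, whose values equal the glutamine column, set the mapping.

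The lowest RPM values rose in fixed steps of 0.264 in the control, 0.0533 in the glucose-deficient and 0.0546 in the glutamine-deficient library, with an added offset of 0.5 fragment per region. After the offset was taken off, each value was rounded to the nearest 0.5 fragment. Below 1000 RPM the largest distance from such a step was 0.00192 fragment in the control, 0.000563 in the glucose-deficient and 0.00366 in the glutamine-deficient library. Over all listed regions, 63.5% of control, 99.97% of glucose-deficient and 99.98% of glutamine-deficient values were then whole fragments. The other control values lay 0.5 fragment from a whole number, as if a lone mate counted as 0.5. Fragments recovered in this way gave library totals, counting intervals and floors.

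A gene's value was the sum of its regions. The ratio of each gene was taken as log2(RPM + 1), which understates the difference of low genes. Genes at 1 RPM or more in either library were tested against a ratio of 2. Intervals of a ratio are exact conditional binomial intervals at 95%, and shares have Poisson intervals. The main ratios and folds are of RPM with the offset, while their intervals are of fragments without it. Such a fold understates the fold of fragments where a library had few fragments. A gene at 0 fragments was set to a floor of 3 fragments only for bounds written as at least and medians at the bound. These bounds leave out the control's counting error and exceed the lower ends of the intervals. For each of 33 gene lists with at least 5 tested members, the median was set among 10000 random lists of the same size matched on mean RPM in 20 bins. These percentiles are not used here, because most members had 0 fragments in the deprived libraries and the ratios followed the control level (r of 0.972 and 0.974 across genes), so a percentile restates abundance within a bin. No p-value was computed, because each group had 1 library.

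The groups, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. The rule names the 10 higher and 10 lower genes of each comparison with the control by absolute log2 ratio, 5 and 5 between the deprived libraries, up to 4 members per list, and the 10 most abundant genes of each library. Y-linked genes and the gene for the X-inactivation transcript, with its antisense partner, are not named. RN7SL1, and the few genes of the closing part outside the rule, were chosen after their values were seen. UBR4 and PRKDC, which the rule places among the 10 highest of the glutamine-deficient library, had 0 fragments there and owe 1.04 and 1.01 RPM to the offset summed over many regions.

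Alternatives were other pseudocounts and filters, the offset taken off, and tests on recovered fragments with total, TMM (edgeR 4.0.16) and median-of-ratios (DESeq2 1.42.0) scaling, filters of 10, 50 and 200 fragments, thinning to the smallest total, and totals without abundant genes. Similarity to the ATF4 mRNA of 2019 nt was searched with blastn 2.17.0 in GENCODE transcripts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. The steps were tested on simulated data: of 200 genes set to a 4-fold difference, 100% of the higher and 99% of the lower were recovered on 5932 genes of the glucose-deficient comparison, with 3 false calls. On 5928 genes of the glutamine-deficient comparison 100% of both were recovered, with 6 false calls. The intervals covered the true ratio for 95.6% and 95.9% of genes. These simulated libraries kept the control's composition, without the ATF4 share of the real deprived libraries. In those, 5393 and 5882 of the lower genes had 0 fragments. The recovery rates therefore do not show that a 4-fold difference could be found in the real libraries.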

Results

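Per the protocol in the labels, RNA captured by the long non-coding RNA DAMER was sequenced from 95D cells, an established human lung cancer line. The labels describe 3 cultures, 1 library each: control medium, glucose-deficient medium and glutamine-deficient medium, the deprivation lasting 48 h. Per the labels, full-length DAMER was transcribed in vitro, biotinylated at its 3′ end and used as bait for RNA in cell lysates. The same pulldown is described for the control culture, while the sample titles name plain RNA sequencing, so what the control library stands for is not settled by the labels. The deposited values, in RPM (reads scaled to a common library total), moved in fixed steps that gave totals of 3781863 fragments for the control, 18775817 for the glucose-deficient and 18301611 for the glutamine-deficient library. A count of 0 fragments allows up to 0.793 RPM in the control, 0.160 RPM in the glucose-deficient and 0.164 RPM in the glutamine-deficient library. With 1 library per condition, no difference has a replicate check and no p-value is given. Intervals are 95% intervals that cover counting error only, since PCR duplicates are not independent molecules.

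The first comparison asks which RNAs differed between the libraries labelled glucose-deficient and control. ATF4, the transcription factor of the amino acid and integrated stress responses, held nearly all fragments of the glucose-deficient library. Its level was 998517 RPM there (99.9% of fragments) and 237 RPM in the control library (0.0237%), a ratio of 4205 (3939 to 4494). Of 5931 genes at 1 RPM or more in either library, 7 were at least 2-fold higher and 5924 at least 2-fold lower in the glucose-deficient library. All regions outside ATF4 and its pseudogenes, listed or not, held 0.0689% of its fragments. The split covers listed genes only, and listed regions held 22.7% of control fragments. Every entry lower in this library had at least 9.5 control fragments, and no tested gene lay between the classes. How the list was chosen is not given, so the split may follow from that choice.

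ATF4 lies at chromosome 22, 39519695 to 39522685, plus strand, in GRCh38 coordinates of GENCODE release 29, and is a protein-coding gene. The next 2 higher genes shared 1 region: ATF4P3, a processed ATF4 pseudogene at chromosome 17, 76225751 to 76226806, lies inside RNF157, a ubiquitin ligase gene at 76142453 to 76240373. That region stood at 652 RPM against 6.48 RPM in the control, 101-fold higher (69.0 to 160), and its reads cannot be assigned to ATF4P3 or RNF157. ATF4P4, a transcribed pseudogene at chromosome 11, 113789231 to 113791366, stood at 142 RPM against 9.92 RPM, summed over 2 listed regions. Reads of ATF4 and its near-identical pseudogenes may be split by the alignment, so the pseudogene values are uncertain. The other 3 higher genes had few fragments. The non-coding RNAs LINC02432 (106 fragments against 0) and LINC00343 (33 against 0) stood at 5.67 and 1.78 RPM, and NOL4L, a protein-coding gene, at 2.42 RPM (45 fragments against 1). The intervals of LINC00343 and NOL4L reached down to ratios of 1.70 and 1.55, and neither was 2-fold higher at a pseudocount of 5 RPM.

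**Figure D1:**
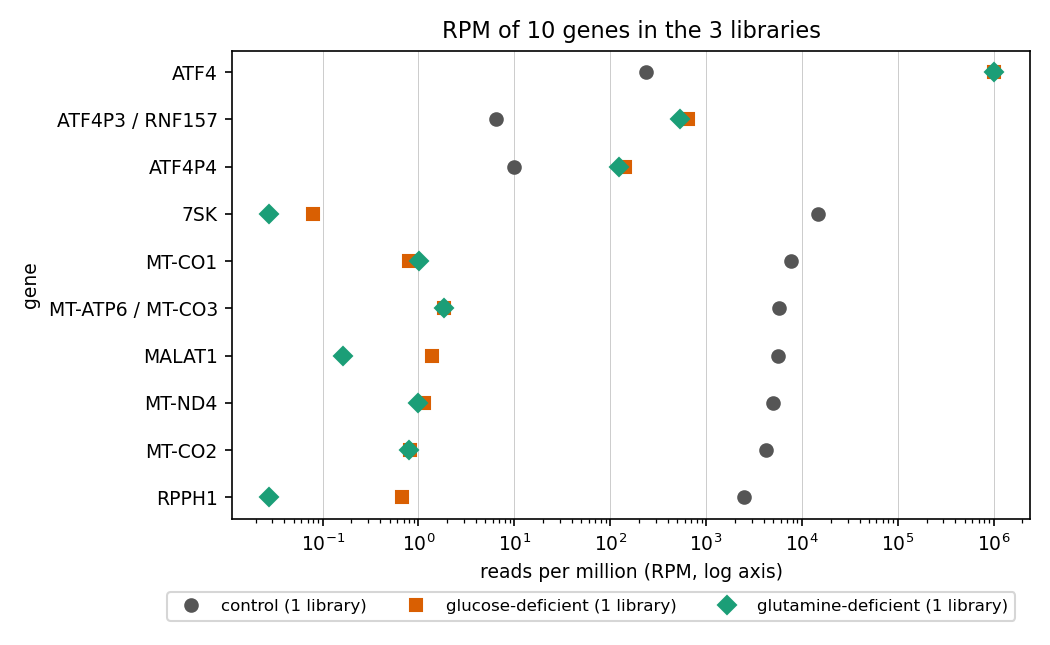
RPM of 10 genes in the 3 libraries on a log axis, 1 point per library and no error bars, since each condition had 1 library. ATF4, the ATF4P3/RNF157 region and ATF4P4 lie to the right of the control in both deprived libraries, and the other 7 genes lie to its left; points at 0 fragments (7SK, MALAT1 and RPPH1 in the glutamine-deficient library) show only the offset of 0.5 fragment per region.

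The most abundant RNAs of the control library were among the lowest log2 ratios, a ranking that follows the control level (r of 0.972 with its negative log2 value). 7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, stood at 14609 RPM in the control and had 1 fragment in the glucose-deficient library. It is listed under 2 identifiers, 7SK and RN7SK, with the same region. Mitochondrial mRNAs of the respiratory chain followed: MT-CO1 was 9683-fold lower (6182 to 18979), MT-CO2 5124-fold (3209 to 9462), and the shared region of MT-ND4 and MT-ND4L 4358-fold (2918 to 7210). The region shared by MT-ATP6, MT-CO3 and MT-ATP8 was 3174-fold lower (2304 to 4652). MALAT1, a nuclear-retained long non-coding RNA, was 4022-fold lower (3029 to 7173) in regions that the antisense gene TALAM1 shares. RMRP, the RNA of RNase MRP, had 1 fragment against 7071, and RPPH1, the RNA of RNase P, 12 against 9353. MALAT1, with 23 fragments against 21061, and RPPH1 were no lower than listed regions outside mitochondria as a whole, which kept 1.09 fragments per 1000 control fragments, so they do not stand out from these.

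Genes fixed in lists by pathway were lower together when reads were scaled by library totals, while 15 of the 21 lists that had a median under the other scalings of the fragments were above 0 under 1 or more of them. Without a pseudocount and with genes at 0 fragments set to their bound of 3 fragments, the median over 5920 tested genes with distinct symbols was −6.61. Genes with 1 or 2 fragments kept those counts, so such medians are not strict bounds and do not compare the deprived libraries. List medians at the bound also follow control levels, so they are not read here as pathway results. In the glucose-deficient library 24 of 28 amino acid, 10 of 13 glycolysis, 19 of 20 glutamine and 47 of 59 ribosomal members had 0 fragments. Their medians under other scalings of the fragments therefore rest mostly on the pseudocount and show no direction. On the amino acid response list, 28 of 40 genes were tested; ATF4 was higher and the other 27 lower. Among those 27, PPP1R15A, the phosphatase subunit that reverses the stress block on translation, was at least 1850-fold lower. The cationic amino acid transporter SLC7A1 and the secreted hormone STC2 each had 1 fragment, against 788 and 671. The list's median log2 ratio was −5.39, and −7.98 without a pseudocount and with members at 0 fragments set to their bound, but 0.11 with median-of-ratios scaling. Of the glycolysis list, 13 members were tested and lower (median −5.82, or −8.62 at the bound, but −0.02 with median-of-ratios scaling). Its members ALDOA and ENO1, an aldolase and an enolase, were at least 669-fold and 660-fold lower, and GAPDH had 6 fragments against 723.5, 514-fold lower (274 to 1638). All 20 tested genes of glutamine metabolism and transport were lower (median −4.34, or −6.99 at the bound), but their median was 1.37 with median-of-ratios scaling, 0.49 with mitochondrial and abundant genes out of the totals and 0.82 with ATF4 and its pseudogenes out of the totals. The transporters SLC38A1 and SLC7A5 were at least 1740-fold and 842-fold lower, and ASNS, asparagine synthetase, had 6 fragments against 252, 141-fold lower (94.5 to 574). All 59 tested cytosolic ribosomal protein genes were lower (median −5.04, or −7.78 at the bound), RPL8 by at least 2285-fold, but their median was 0.79 with median-of-ratios scaling and 0.25 with ATF4 and its pseudogenes out of the totals. The 8 tested mitochondrial mRNAs had a median of −11.09 (−12.12 without a pseudocount, −2.48 with TMM and −1.04 with median-of-ratios scaling), at high control levels: mitochondrial regions kept 0.921 fragments per 1000 control fragments (0.740 to 1.13), close to the 1.09 (1.02 to 1.17) of regions outside mitochondria. The 16 tested nuclear or structural non-coding RNAs had a median of −5.33 (−7.97 at the bound, and −0.94 with median-of-ratios scaling).

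Every tested member of the remaining lists was also lower in the glucose-deficient library on the RPM scale. These were 18 aminoacyl-tRNA synthetases, with YARS1 at least 1602-fold lower, and 18 endoplasmic reticulum chaperone and degradation genes, with the chaperone HSPA5 at 1 fragment against 999.5. Metabolic lists gave 6 MondoA/ChREBP targets, 5 cholesterol, 9 fatty acid, 16 nucleotide and 8 serine and one-carbon genes, among them PHGDH of serine synthesis, at least 586-fold lower. Proliferation lists gave 23 mitotic genes, 34 DNA replication genes and 29 replication-dependent histones, among them the mitotic gene CENPF, at least 1139-fold lower. Stress lists gave 7 p53 targets, 18 autophagy and lysosome genes, 10 NRF2 targets, 14 cytosolic heat shock proteins, 4 hypoxia genes and 8 immediate early genes, with MYC at least 938-fold lower. The rest were 46 nuclear-encoded oxidative phosphorylation genes, 8 snoRNA host genes, 9 interferon-stimulated genes with IFIT2 at least 2122-fold lower, 2 NF-kB, 3 epithelial and 6 mesenchymal genes. Of the markers of other cell types, 1 leukocyte gene (CSF1R) and 1 neuronal gene (NCAM1) were tested and lower, and 0 fibroblast, endothelial or erythroid markers were listed. Reads outside ATF4 and its pseudogenes were 0.0689% of this library against 99.97% of the control, which alone lowers every other gene. With that family out of the totals, 0 fragments would pass 2-fold only from 2225 control fragments upward. Each list member given a bound, here or above, had fewer, so these bounds do not show losses of single genes.

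Of the 5924 lower genes, 5393 had 0 fragments in the glucose-deficient library, so for those genes the data give a bound and no level. The counts rest on scaling by all reads: with TMM scaling of the recovered fragments 124 genes were higher and 924 lower, with median-of-ratios scaling 1657 and 165, with mitochondrial and the 10 most abundant genes out of the totals 442 and 512, and with ATF4 and its pseudogenes out of the totals 923 and 354. On that last scaling 7 were higher and 12 lower when the whole counting interval had to lie beyond 2-fold. The median log2 ratio of all tested genes, −3.92 as reported, was −0.38, 1.06, 0.19 and 0.52 under these scalings in turn. Median-of-ratios factors rest on the 23 of 5928 genes with fragments in all 3 libraries. Only 531 of the 5924 lower genes had a fragment in the glucose-deficient library. Most of the 1657 were therefore at 0 fragments and owe that call to the pseudocount.

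**Figure D2:**
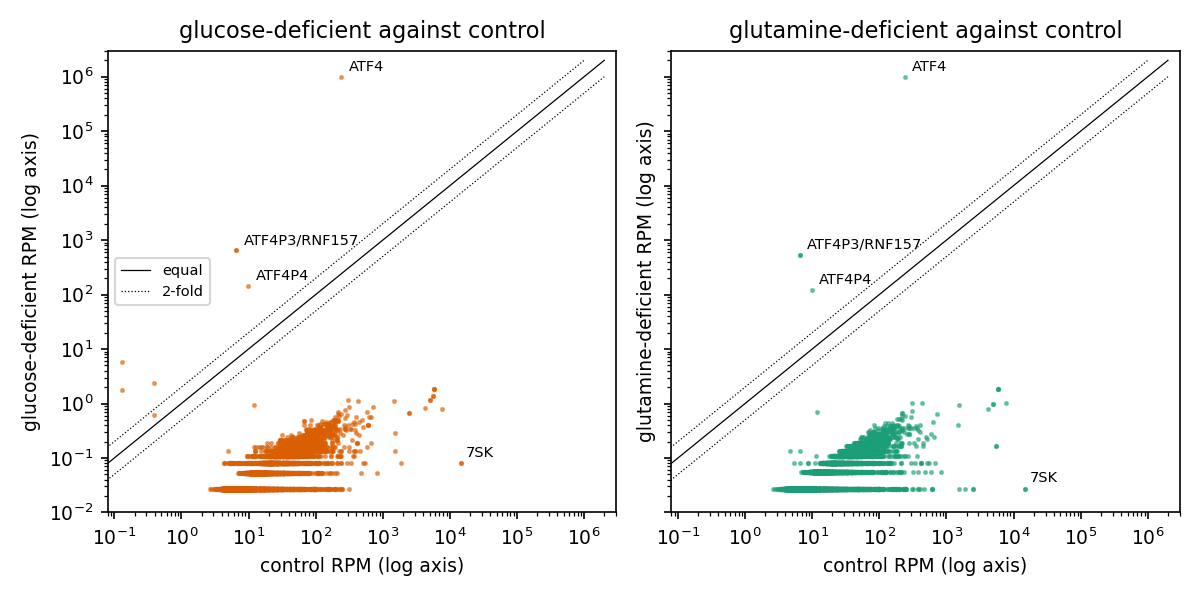
RPM in each deprived library (vertical log axis) against RPM in the control (horizontal log axis), 1 point per gene, with lines for equal and 2-fold different values. ATF4, the ATF4P3/RNF157 region and ATF4P4 lie above the lines in both panels and nearly all other genes lie below on this RPM scale; the horizontal bands at the bottom are genes at or near 0 fragments, whose values are the offset of 0.5 fragment summed over a gene's regions.

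The second comparison asks the same of glutamine-deficient against control cells. ATF4 again held nearly all fragments, 998557 RPM against 237 RPM, a ratio of 4205 (3939 to 4495). Of 5928 tested genes, 4 were at least 2-fold higher, namely ATF4, ATF4P3, RNF157 and ATF4P4, and 5924 at least 2-fold lower. This split too covers listed genes only and may follow from how the list was chosen. The shared region of ATF4P3 and RNF157 stood at 531 RPM, 81.9-fold above the control (56.2 to 131), and ATF4P4, with 1 listed region here, at 123 RPM against 9.78 RPM. LINC02432, LINC00343 and NOL4L are not in the list of this library, so their levels there were not analysed here.

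Nuclear and structural non-coding RNAs had 0 fragments in this library at large control levels. 7SK was at least 89123-fold lower, MALAT1 at least 33978-fold, RPPH1 at least 15088-fold, RMRP at least 11407-fold and RN7SL1, the RNA of the signal recognition particle, at least 9266-fold lower. These bounds follow the control level and do not rank the genes. Mitochondrial mRNAs kept fragments: MT-CO1 had 17 and was 7653-fold lower (5200 to 14298), MT-CO2 had 14 and was 5339-fold lower (3295 to 10116), and MT-ND4 with MT-ND4L was 5074-fold lower (3210 to 8564). The 8 tested mitochondrial mRNAs had a median log2 ratio of −11.11 (−12.00 without a pseudocount, and −0.68 with median-of-ratios scaling).

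Each of the 33 lists had as many tested and as many lower members as in the glucose comparison, and the medians of the amino acid, glycolysis, glutamine and ribosomal lists were above 0 with median-of-ratios scaling (0.37, 0.14, 1.26 and 0.71), and that of the glutamine list also with TMM (0.014) and with ATF4 and its pseudogenes out of the totals (0.27). Of the tested members of these 4 lists, 27 of 28, 12 of 13, 20 of 20 and 59 of 59 had 0 fragments here. The sign of such medians follows the scaling, the pseudocount and the control level, so it shows no direction. Over 5917 tested genes with distinct symbols the median at the bound was −6.50, a value not comparable with that of the glucose comparison. In the amino acid response list ATF4 was higher and 27 genes were lower (median −5.38, or −8.09 at the bound), with PPP1R15A at least 1803-fold, SLC7A1 at least 1277-fold and STC2 at least 1086-fold lower. The glutamine metabolism list, closest to the deprivation, had 20 lower genes (median −4.34, or −6.96 at the bound), with SLC38A1 at least 1696-fold, the glutamine transporter SLC1A5 at least 450-fold and ASNS at least 411-fold lower. The 13 glycolysis genes had a median of −5.82 (−8.59 at the bound), with GAPDH at least 1169-fold lower. The 59 ribosomal protein genes had a median of −5.04 (−7.64 at the bound), with RPL8 at least 2227-fold lower. The 16 structural non-coding RNAs had a median of −5.33 (−7.93 at the bound). IFIT2 was at least 2069-fold, MYC at least 914-fold and the chaperone HSPA5 at least 1616-fold lower. Reads outside ATF4 and its pseudogenes were 0.0790% of this library against 99.97% of the control. With that family out of the totals, 0 fragments would pass 2-fold only from 1943.5 control fragments upward. Each gene given a bound in these lists had fewer, so the bounds do not show losses of single genes.

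Of the 5924 lower genes, 5882 had 0 fragments in the glutamine-deficient library. With TMM scaling 159 genes were higher and 746 lower, with median-of-ratios scaling 1738 and 207, with mitochondrial and the 10 most abundant genes out of the totals 114 and 762, and with ATF4 and its pseudogenes out of the totals 516 and 601 (4 and 25 by whole counting interval), while the median of all tested genes went from −3.93 to −0.09, 1.16, −0.11 and 0.16. Only 42 of the lower genes had a fragment in this library. Except by whole counting interval, most genes called higher under these scalings were therefore at 0 fragments and owe the call to the pseudocount. Median-of-ratios factors rest on the 23 of 5928 genes with fragments in all 3 libraries.

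The third comparison sets the deprived libraries against each other. ATF4, the shared region of ATF4P3 and RNF157, and mitochondrial mRNAs differed by less than 2-fold, while MALAT1 was higher in the glucose-deficient library. ATF4P4 stood at 142 and 123 RPM, but these sum 2 listed regions in the glucose block and 1 in the glutamine block. Its entry with the same control value in both blocks, 9.78 RPM, stood at 48.8 RPM (915 fragments) in the glucose-deficient library. In the glutamine-deficient library that entry stood at 123 RPM (2244.5 fragments), so the ratio of ATF4P4 depends on which regions are summed. Only 16 genes reached 1 RPM in either library: 3 were at least 2-fold higher in the glucose-deficient library, 0 were lower and 13 were neither. These counts depend on the settings: 0 were higher with a pseudocount of 5 RPM, 511 were higher and 24 lower when 1 fragment was enough for testing, and 12 genes were tested, 3 of them higher, with the offset taken off. The higher ones were MALAT1 and TALAM1, which share their regions, with 23 fragments against 0 (1.38 RPM against a floor of 0.164 RPM), and 1 further gene not named here. The 6 tested mitochondrial mRNAs, most of which share a region with another, were all within 2-fold.

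Fragments left in listed regions outside the ATF4 family differed in kind between the deprived libraries. Of the 12936 and 14450 fragments outside the family in the glucose-deficient and glutamine-deficient library, 8.95% and 1.11% lay in listed regions; the rest were in regions not listed and were not analysed here. In listed regions lower than the control and outside mitochondria, the glucose-deficient library kept 830 fragments, or 1.09 per 1000 control fragments (1.02 to 1.17), and the glutamine-deficient library 34, or 0.0446 per 1000 (0.0309 to 0.0624). Scaled by totals, the glucose-deficient library was 23.8-fold above the glutamine-deficient one (16.9 to 34.6). In mitochondrial regions both kept similar numbers, 89.5 and 99.5 fragments, a ratio of 0.877 (0.652 to 1.18). Protein-coding regions kept 1.21 per 1000 in the glucose-deficient and 0.0460 per 1000 in the glutamine-deficient library.

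**Figure D3:**
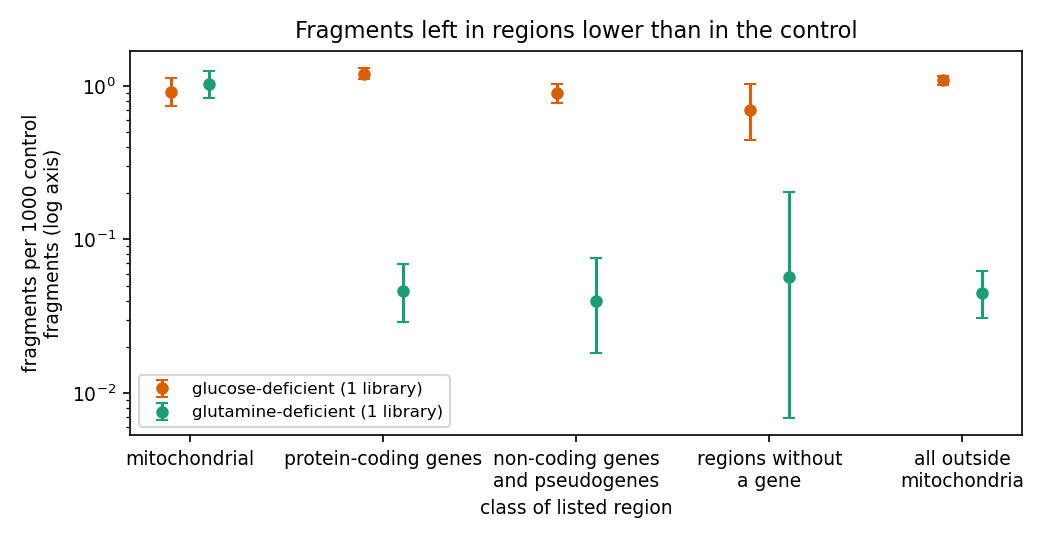
Fragments in each deprived library per 1000 control fragments (log axis) over 5 classes of listed regions that were lower than in the control, with 95% Poisson intervals that cover counting error only. Outside mitochondria the glucose-deficient library lies near 1.09 and the glutamine-deficient library near 0.0446, while for mitochondrial regions the points stand at 0.921 and 1.02.

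The log2 ratios of both deprived libraries over the control had a Pearson r of 0.999 across 5928 genes (0.832 on recovered fragments with at least 50), which are not independent replicates. They share the control library, and 100 simulated sets of unchanged libraries gave a median r of 0.823 (0.808 to 0.835). These sets were drawn from the pooled profile of all 3 libraries, which is mostly ATF4. Other genes are scarcer in them than in the real control, so they are no close match for the observed r, covariance or overlap. The covariance was 1.999 against 0.103 in the simulated sets, a difference of 1.90, and each set of ratios had an r of 0.972 or 0.974 with the negative log2 control level alone. Among genes in both tables, 4 were higher in both, against 0.0027 for independent lists, which leave out the shared control, and a median of 2 (0 to 6) in the simulated sets. The 4 are ATF4, ATF4P3, RNF157 and ATF4P4, members of 1 sequence family or in its regions, so they are not 4 independent genes. Lower in both were 5924 genes, against 5920 for independent lists and a median of 5 (0 to 13) in the simulated sets. With 1 control library the control cannot be split, so part of the excess may come from sharing it.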

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

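All tests in this part were chosen after the results were seen. One signal lay outside the gene comparisons: a region that names no gene stood at 1.41 RPM in the glucose-deficient library, with 26 fragments against 0 in the control and a ratio of at least 1.32 by its counting interval. In the glutamine-deficient library a region without a gene had 15 fragments against 0, with an interval that included 1.

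The first pattern is that nearly all fragments of both deprived libraries lay at ATF4. Bait RNA read out in every pulldown stays open: the control held 0.0237% of its fragments at ATF4, which would argue against it only if the control was a pulldown too, and protocol and titles differ on that. RNA with ATF4 sequence added or amplified in the deprived libraries alone cannot be told apart from capture of cellular ATF4 RNA: either would give the share of 99.9% seen in both, and the DAMER sequence was not used here. The higher values at ATF4P3 and ATF4P4 are consistent with ATF4 reads placed at near copies, since these are 97.5% and 96.9% identical to the ATF4 mRNA, while ATF4P1 and ATF4P2, at 88.3%, are not listed and RNF157 transcripts have no match. A biological difference between cultures stays open and was not tested.

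The second pattern is that nearly all other listed genes were lower in both deprived libraries. In 20 simulated draws that only diluted the control evenly, 5924 genes were lower in every draw of each comparison, so the count itself is what dilution by 1 abundant RNA would give. The first test of an even dilution was the mitochondrial share of reads outside the ATF4 family, which was 3.72-fold (3.01 to 4.60) and 3.73-fold (3.05 to 4.57) below the control; it decides nothing alone, because the share of all listed regions was also 2.54-fold (2.39 to 2.69) and 20.4-fold (17.6 to 24.1) lower, the rest of these reads was unlisted and its source is unknown. The ratio of listed fragments outside mitochondria to mitochondrial ones was then chosen after that first result, because it does not need the total: it was 7.83 in the control, 9.27 (7.41 to 11.6) in the glucose-deficient and 0.342 (0.223 to 0.506) in the glutamine-deficient library, which argues against an even dilution in the latter alone. In the glucose-deficient library single regions departed from control proportions, with a chi-square per degree of freedom of 9.12 over 16 regions (5.69 without 7SK) against at most 1.90 in 100 draws, while the structural non-coding RNA list without 7SK, at 1.03 fragments per 1000 control fragments, decides nothing; dilution together with a difference in the other RNAs stays open.

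The third pattern is that fragments of nuclear genes remained in the glucose-deficient but hardly in the glutamine-deficient library. Lower depth is argued against, since the glutamine-deficient library had 97.5% of the other's fragments. Carry-over of the control library as the whole source is argued against by the same chi-square of 9.12 and by 7SK, with 1 fragment against 59.2 expected, although a part from carry-over could remain. PCR duplicates would widen the chi-square, and a difference between the cultures was not tested.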

How the results depend on the processing

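Other pseudocounts and filters on RPM were planned. The settings on fragments were planned for deposited counts, but fragments had to be recovered from RPM, a step devised after the values were seen. Taking the offset off and leaving ATF4 and its pseudogenes out of the totals were also added then. No paired analysis was possible because each group had 1 library. Upper-quartile scaling was not run, since the upper quartile of both deprived libraries was 0 fragments. Of 17 settings, other pseudocounts and filters on RPM kept the counts over the control within 1.5 times. Of the named genes, 451 values kept their side of the threshold and 6 lost it: LINC00343, NOL4L, MALAT1 and TALAM1 at a pseudocount of 5 RPM, and MT-ATP6 and MT-CO3 with median-of-ratios scaling. The r of the responses went down to 0.832 with at least 50 fragments and 0.779 with at least 200; the shared control holds it high, so its range shows no stability.

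Glucose-deficient over control, main 7 higher and 5924 lower, gave 124 and 924 with TMM, 1657 and 165 with median-of-ratios, 442 and 512 without mitochondrial and the 10 most abundant genes, and 923 and 354 without ATF4 and its pseudogenes. Asking also for the whole interval beyond 2-fold left 12 lower. Filters reduce the number tested: 3148 were lower at 50 fragments, with a pseudocount of 5 fragments, and by interval, 4 higher and 853 lower at 200 fragments, and 4 and 3163 after thinning. Glutamine-deficient over control, main 4 and 5924, gave 159 and 746 with TMM, 1738 and 207 with median-of-ratios, 114 and 762 without mitochondrial and abundant genes, 516 and 601 without ATF4 and its pseudogenes, and 25 lower by interval on that scale. It gave 3148 lower at 50 fragments, with a pseudocount of 5 fragments and by interval, 853 at 200 fragments and 3163 after thinning. Between the deprived libraries, main 3 higher and 0 lower, there were 0 higher at a pseudocount or filter of 5 RPM, at 200 fragments and after thinning. There was 1 higher at 50 fragments under every scaling, by interval and with a pseudocount of 5 fragments. A filter of 10 fragments gave 7 higher and 1 lower, and a filter of 1 fragment 511 and 24.

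All 25 lists had a median below 0; with at least 50 fragments 21 lists had enough members, all below 0 under total scaling, and with at least 200 fragments 10 had, with 10 and 10 below 0. Of the 21, median-of-ratios left 6 below 0 in the glucose and 3 in the glutamine comparison, totals without mitochondrial and abundant genes 12 and 16, totals without ATF4 and its pseudogenes 9 and 14, and TMM 15 in the glutamine comparison. Without a filter 24 lists lay below 0 between the deprived libraries, against 0. The median of all genes was then −0.00097, the difference that the offset alone gives a gene at 0 fragments in both. That count therefore shows no direction. Over all lists and settings, 73 of 668 medians reversed, in 15 lists of the glucose and 18 of the glutamine comparison, 61 were no longer beyond 2-fold and 534 kept their side. All reversals came with TMM, median-of-ratios or totals without abundant genes or the ATF4 family. Only the 6 lists whose medians the report gives are given one by one, a choice made after the medians of all lists were seen. In the glucose comparison, median-of-ratios gave 0.11 for the amino acid response, 1.37 for glutamine metabolism and 0.79 for ribosomal proteins. Glutamine metabolism was 0.49 without mitochondrial and abundant genes and 0.82 without the ATF4 family, where ribosomal proteins were 0.25. In the glutamine comparison, median-of-ratios gave 0.37 for the amino acid response, 0.14 for glycolysis, 1.26 for glutamine metabolism and 0.71 for ribosomal proteins. Glutamine metabolism was 0.014 with TMM and 0.27 without the ATF4 family. The lower depth of tested genes in the deprived libraries limits all of these: most had 0 fragments there, so a scaling that raises the libraries moves genes at 0 with their pseudocount. Beyond that the cause was not tested.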

Other observations

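All tests in this part were chosen after the results were seen, and RN7SL1, MT-RNR2, NCL, EEF2, PRRC2C and SRRM2 were named after their values were seen. With ATF4 and its pseudogenes out of the totals and the whole counting interval beyond 2-fold, 12 genes were lower and 7 higher in the glucose-deficient library; 4 of the higher ones were ATF4, its pseudogenes and RNF157, and the others were LINC02432 and ASNS with a gene that shares its region. Listed regions as a whole were 2.54-fold lower on this scale in the glucose-deficient and 20.4-fold lower in the glutamine-deficient library, so lower values of single genes include that shift. Genes that share regions are each counted, as with 7SK and RN7SK, MALAT1 and TALAM1, or MT-ND4 and MT-ND4L. The counts of lower genes are therefore not counts of independent signals. The lower genes included 7SK, 189-fold (33.9 to 7467), RMRP, 24.2-fold (4.34 to 956), RN7SL1, 9.83-fold (2.72 to 81.2), and MT-CO1, 7.41-fold (4.26 to 13.1). The ribosomal RNA MT-RNR2 had 0 fragments against 3129.5. In the glutamine-deficient library 25 genes were lower on this scale, among them MT-CO1, 6.58-fold (4.11 to 11.3), and NCL, EEF2, PRRC2C and SRRM2 at 0 fragments. Their products bind nucleolar RNA (NCL), move the ribosome (EEF2) or belong to nuclear speckles (SRRM2). Only 29 and 31 genes were abundant enough in the control for 0 fragments to pass. In 20 simulated even dilutions 0 genes were lower in any draw. Those draws kept listed regions at 22.7% of reads outside the ATF4 family, as in the control. The real shares were 8.95% in the glucose-deficient and 1.11% in the glutamine-deficient library. The draws therefore do not test the lower genes against that shift.

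The amino acid gene ASNS was higher on this scale in the glucose-deficient library, with 6 fragments against 252, a ratio of 6.96 (2.53 to 15.4). A hypothesis is that known ATF4 targets may be held at a higher level among the remaining reads. Over the 27 listed ATF4 targets the library had 8 fragments, 1.17 per 1000 control fragments (0.507 to 2.31), against 1.09 over all regions outside mitochondria. Without ASNS the value was 0.305 (0.0369 to 1.10), and the glutamine-deficient library had 0 fragments of these genes. The fragments are too few to decide, and simulated even dilutions gave up to 8 higher genes on this scale.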
